A study of Mus musculus with 2 samples.

How the data were processed

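RNA from 2 primary cell cultures of C57BL/6J mice was compared, 1 library of embryonic fibroblasts and 1 of bone marrow derived macrophages. Per the labels, the fibroblasts came from embryos of day 13.5 to 14.4, were used at passage 4 to 7 and were collected from 100000 cells, and the macrophages were differentiated for 6 days and collected from 750000 cells. Both media held 10% serum, and the macrophage medium also 30% L929-conditioned medium. Per the labels' protocols, libraries were made with a stranded poly(A) kit (Illumina TruSeq) and sequenced on a NextSeq instrument in paired reads of 76 bp. Per the submitters' processing notes, kallisto 0.43.1 and the build GRCm38 were used. The transcript set, the way transcripts were joined into genes and any filter are not given in the sources used here.

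The deposited values are transcripts per 1000000 (TPM) by their range and totals, since the file names no unit: each column is non-negative, not whole, and sums to just under 1000000. The table held 34456 rows named by gene symbol. Rows sharing a symbol were added, which gave 34295 genes; 158 symbols stood on more than 1 row, and for 129 of them the rows held identical values, so that the sum counts a value double where such rows are copies. Among the rows, 28 carried date-like names, as spreadsheet programs make of some symbols. They were kept apart by their descriptions and are part of the 34295 genes and of the counts over all genes, but none is named here. Of the gene symbols, 32189 (93.9%) matched GENCODE M21, an annotation of GRCm38, and 21539 of these were protein coding. Coordinates come from that annotation. Symbols are those of the table.

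TPM are shares of a library and keep no depth, so no interval or detection limit can be computed. Exact zeros may be failed estimates. A value of 0, whether given as listed at 0 or as against 0, is therefore only the listed value, and no fold is given for it. The fibroblast library had 12561 genes at 1 TPM or more and the macrophage library 11429. The 10 highest genes held 6.47% and 12.5% of the TPM, mitochondrial genes 4.83% and 2.97%, and ribosomal protein genes 14.1% and 9.89%, in the fibroblast and macrophage libraries.

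With 1 library per group no test was run. The size rule, the gene lists, the ligand and receptor pairs, the rule for named genes and all alternatives but 1 were set before the data were examined. A gene is called higher in a library where the log2 ratio of TPM plus 1 is at least 2 (4-fold) and its value there is at least 5 TPM. The added 1 pulls the log2 ratios of low genes toward 0. Folds given in words are ratios of the TPM themselves. A gene is detected at 1 TPM or more in either library, and expressed at 5 TPM or more. A list's median log2 ratio is taken over its detected members and set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these libraries and is no test of the cell types.

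Named genes are the 3 genes of the sort, the detected members among Csf1, Il34, Csf1r, the PDGF ligands, Pdgfra and Pdgfrb, and in each list up to 4 genes per direction past the size rule with the highest value. Where a list had no such gene, up to 2 with the highest value were taken. Among all genes, the 10 per direction with the largest log2 ratio at 100 TPM or more were added, leaving out genes that name no protein or known RNA. Genes outside this rule that make up a small count or a pair were chosen after their values were seen. Some genes that the rule takes are not reported here.

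The lists were macrophage and fibroblast markers and the sort genes; ligand and receptor families (PDGF and VEGF, colony-stimulating and stem cell factors, EGF, FGF, TGF-beta, IGF and HGF, neurotrophins, angiopoietin with GAS6 and pleiotrophin); cytokines, chemokines and their receptors; Wnt, Hedgehog and Notch; matrix, contractile and protease genes. Further lists covered the lysosome, pattern receptors, complement and Fc receptors, MHC class II, interferon-stimulated genes, the cell cycle and its inhibitors, immediate early genes, cholesterol synthesis, lipid handling, glycolysis, Hox genes, imprinted genes and lineage factors. Markers of 11 other cell types were included, with mitochondrial genes, genes used in every cell, and Y-linked genes as signs of library state.

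Alternatives were a pseudocount of 0.1 or 5, a minimum of 1 or 10 TPM or none, a 2-fold threshold, median-of-ratios scaling, rescaling without mitochondrial genes and the 50 highest genes of each library, the highest single row of a gene, protein-coding genes alone, and random lists without matching. After the data were seen, a further alternative subtracted from each library the median share at which abundant markers of the other cell type appeared in it.

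The procedure was tested on simulated data made from the 34295 genes of this comparison. With a simulated noise of SD 0.2 on the log2 scale, set without replicates to draw it from, the size rule called 100 of 100 genes changed 8-fold, 0 of 100 changed 2-fold and 0 of 34095 unchanged genes. The noise is small beside the threshold, so these counts check the code and not the error of the calls. Of 100 unchanged lists, 88 lay between the 5th and 95th percentile, and 20 of 20 lists raised 2-fold lay above the 95th. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.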

Results

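Poly(A) RNA was sequenced from 2 kinds of primary C57BL/6J mouse cells, with 1 library each. Embryonic fibroblasts were grown out of midgestation embryos freed of head and red organs, and cells carrying the leukocyte and macrophage surface proteins CD45, CD11b or F4/80 were removed by sorting. Macrophages were grown from bone marrow in medium holding 30% conditioned medium of L929 cells, a fibroblast line whose medium is the usual source of the macrophage growth factor CSF1. The series set out to survey growth factors and their receptors in both cell types. Values are transcripts per 1000000 transcripts (TPM) of each gene, which summed to 999545 in the fibroblast library and 999609 in the macrophage library. There were no replicates, so no error, test or p-value can be given, and TPM keep no read depth, so the depth of each library is unknown. A gene is called higher in 1 library where its value plus 1 was at least 4-fold that of the other and it reached 5 TPM or more there. Each difference describes these libraries without a replicate check, and cell type cannot be separated from culture medium, cell number and preparation.

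Marker genes separated the libraries by cell type. Of 22 macrophage markers, 22 were higher in the macrophage library, with a median log2 ratio of fibroblast over macrophage of -8.15. Among them were Lyz2, which encodes lysozyme, at 12375 TPM against 19.4, and Cd68 at 3092 against 9.47. Of 24 fibroblast markers, 20 were higher in the fibroblast library, with a median log2 ratio of 7.45 over the 23 detected. The collagen genes Col1a1 and Col1a2 stood at 2634 and 1833 TPM there, against 3.66 and 3.53. The 3 detected fibroblast markers that did not differ by the rule were named after their values were seen: Vim at 5487 TPM against 4097, S100a4 at 3650.3 against 2645, and Pdpn at 89.8 against 49.3, the sum of 2 identical rows. The mesenchymal factor gene Tcf21, also named afterwards, was below 1 TPM in both libraries. The genes of the 3 surface proteins used to clear the fibroblasts of macrophages were low in the fibroblast library: Ptprc, encoding CD45, at 0.352 TPM, Itgam, encoding CD11b, at 0.483, and Adgre1, encoding F4/80, at 0.457. In the macrophage library they stood at 142, 303 and 399 TPM.

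Across all genes, 11191 reached 5 TPM in at least 1 library and 8363 in both. Of the 11191, 1602 were higher in the fibroblast library and 981 in the macrophage library, together 23.1%. Among genes at 100 TPM or more the order was opposite, with 272 higher in the fibroblast and 309 in the macrophage library. The 10 largest differences toward fibroblasts were led by matrix and contractile genes: Col3a1 at 1318 TPM against 1.18, Col1a1, the proteoglycan gene Bgn at 2988 against 4.38, Sparc at 3888 against 6.15, smooth muscle actin Acta2 at 4751 against 7.80, and the collagen crosslinking enzyme gene Lox at 1625 against 2.02. The other 4 were Fbln2, Wisp2, Prss23 and the growth factor gene Igf2, with log2 ratios between 9.05 for Fbln2 and 8.74 for Igf2. Toward macrophages the signalling adaptor genes Fcer1g and Tyrobp stood at 3346 and 3085 TPM against 1.54 and 2.00. The complement genes C1qa, C1qb and C1qc reached 2049, 3514 and 2689 TPM, against 1.01, 2.21 and 2.23. The remaining 5 were Lilrb4a, the lysosomal protease gene Ctss, Mpeg1, Ms4a7 and the chemokine gene Ccl12, at 2829, 2931, 1606, 1139 and 629 TPM. Lilrb4a was the sum of 2 differing rows, and its highest single row gave a log2 ratio of -9.19 in place of -9.79. Ccl12 was listed at 0 in the fibroblast library. Spearman's rho between the libraries was 0.55 across the 11191 genes, which are not independent replicates. Genes at 5 TPM or more in both libraries had a median log2 ratio, here taken without the added 1, of 0.18 toward the fibroblast library. Median-of-ratios scaling, which brought it to 0.013, gave 1494 and 1059 genes.

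The comparison for which the series was made was that of growth factor genes, and those past the size rule lay mostly on the fibroblast side. Of 95 listed ligand genes, 56 were detected at 1 TPM or more in at least 1 library. Of these, 26 were higher in fibroblasts, 5 in macrophages and 25 in neither, with a median log2 ratio of 2.08, above every one of 10000 random lists of the same size and expression. Of 62 listed receptor genes, 43 were detected, of which 18 were higher in fibroblasts, 7 in macrophages and 18 in neither, with a median log2 ratio of 1.21.

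**Figure D1:**
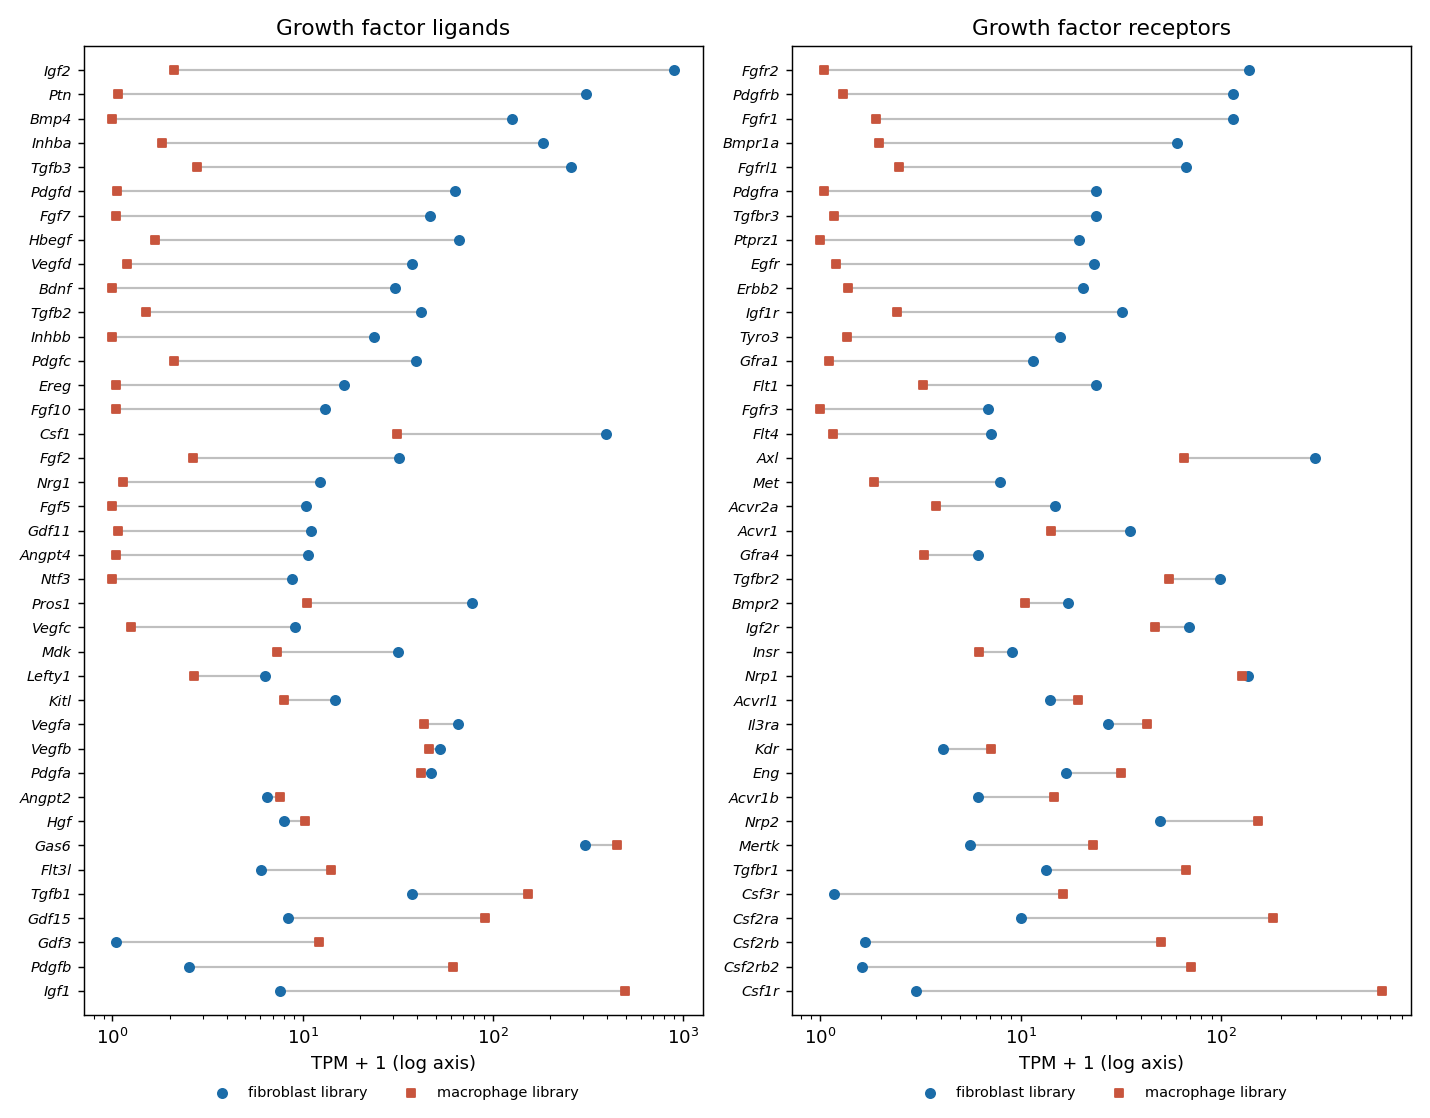
Growth factor ligand genes (left) and receptor genes (right) at 5 TPM or more in at least 1 library, apart from any not reported here, on a log axis of TPM plus 1, ordered by the ratio between the libraries; circles are the fibroblast library and squares the macrophage library, 1 library each. Igf2, at 901 TPM against 1.11, leads the ligands on the fibroblast side, and Csf1r, at 640.0 TPM against 2.00, is the receptor farthest to the macrophage side.

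The colony-stimulating factor system was split between the cell types. Csf1, which encodes the main survival and growth factor of macrophages, stood at 395 TPM in fibroblasts and 30.5 TPM in macrophages, a 12.9-fold difference. It lies on the minus strand of chromosome 3 at 107741048 to 107760469 (GRCm38, gene ENSMUSG00000014599). Il34, whose product binds the same receptor, stood at 1.70 TPM in fibroblasts and was listed at 0 in macrophages. Their receptor gene Csf1r, on the plus strand of chromosome 18 at 61100598 to 61132149 (ENSMUSG00000024621), stood at 640.0 TPM in macrophages and 2.00 TPM in fibroblasts, a 320.2-fold difference. Of the 9 ligands of this family, 5 were detected and Csf1 alone differed by the rule. Of its 10 receptors, 6 were detected and 5 were higher in macrophages, with a median log2 ratio of -4.55. Besides Csf1r these were the granulocyte-macrophage factor receptor gene Csf2ra at 181 TPM against 8.99, and Csf2rb2 at 69.9 against 0.620. The other 2 were Csf2rb at 49.5 against 0.671 and Csf3r, named after its values were seen, at 15.2 against 0.164. Csf3r is also a neutrophil gene, and 5 of 11 neutrophil genes were higher in the same library. Csf2rb and Csf2rb2 are near-identical copies, so the division of reads between them is uncertain.

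The platelet-derived growth factor system had its receptors in fibroblasts and its ligands in both cell types. Pdgfrb stood at 114 TPM in fibroblasts and 0.304 in macrophages, and Pdgfra at 22.9 and 0.0422. Pdgfrb lies just upstream of Csf1r on the plus strand of chromosome 18, at 61045150 to 61085061 (ENSMUSG00000024620), and Pdgfra on the plus strand of chromosome 5 at 75152292 to 75198215 (ENSMUSG00000029231). Of the ligands, Pdgfb was the one higher in macrophages, at 60.8 TPM against 1.54, a 39.5-fold difference. Pdgfa did not differ by the rule, at 40.7 TPM in macrophages and 46.5 in fibroblasts. Pdgfc and Pdgfd were higher in fibroblasts, at 38.5 TPM against 1.12 and 62.6 against 0.0569. Pdgfa lies on the minus strand of chromosome 5 at 138976014 to 138997370, Pdgfb on the minus strand of chromosome 15 at 79995874 to 80014977, Pdgfc on the plus strand of chromosome 3 at 81036416 to 81214040, and Pdgfd on the plus strand of chromosome 9 at 6168584 to 6378850. In the whole family of 9 PDGF and VEGF ligands, 4 were higher in fibroblasts, 1 in macrophages and 4 in neither, with a median log2 ratio of 1.26. The lymphatic factor genes Vegfd and Vegfc were among the former, at 36.6 and 8.14 TPM against 0.197 and 0.260. Of the 7 receptors, 4 were higher in fibroblasts, with a median log2 ratio of 2.63, and the remaining members Flt1 and Flt4 stood at 22.8 and 6.14 TPM against 2.27 and 0.154.

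The insulin-like growth factors were divided between the cell types in opposite directions. Igf2 stood at 901 TPM in fibroblasts and 1.11 in macrophages, whereas Igf1 stood at 6.57 in fibroblasts and 493 in macrophages, a 75.0-fold difference. The receptor gene Igf1r was higher in fibroblasts, at 31.0 TPM against 1.43, and so was the hepatocyte growth factor receptor gene Met, at 6.90 against 0.847. Over the 4 IGF and HGF ligands, 1 was higher in each library and 2 in neither, with a median log2 ratio of -0.54. Over their 5 receptors, 4 were detected and 2 were higher in fibroblasts, with a median of 1.33. The ligand and receptor medians lay at percentiles 10.23 and 85.19 of matched random lists.

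Transforming growth factor genes were likewise divided by member. Tgfb3, Inhba, Bmp4 and Tgfb2 were higher in fibroblasts, at 257, 182, 126 and 40.8 TPM against 1.77, 0.813, 0 and 0.496. Tgfb1, Gdf15 and Gdf3 were higher in macrophages, at 152, 89.6 and 11.2 TPM against 36.5, 7.41 and 0.0463. Of these, Tgfb1 lay close to the 4-fold limit. Of 14 detected ligands of the family, 6 were higher in fibroblasts and 3 in macrophages, with a median log2 ratio of 2.27. Of 11 detected receptors, 8 did not differ by the rule and the median was 0.85. Bmpr1a and Tgfbr3 were higher in fibroblasts, at 59.3 and 22.7 TPM against 0.956 and 0.174, and Tgfbr1 in macrophages, at 65.8 against 12.4.

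In the remaining families Mertk was the 1 gene past the size rule toward macrophages. All 4 detected fibroblast growth factor receptor genes were higher in fibroblasts, with Fgfr2 at 138 TPM against 0.0425, Fgfr1 at 114 against 0.893, the decoy receptor Fgfrl1 at 66.0 against 1.48 and Fgfr3 at 5.84 against 0. Their ligands Fgf7, Fgf2, Fgf10 and Fgf5 were also higher in fibroblasts, at 45.9, 31.1, 12.2 and 9.45 TPM against 0.0456, 1.65, 0.0474 and 0. The medians were 5.34 for these receptors and 3.49 for the 6 detected ligands. The epidermal growth factor family gave the same direction, with 3 of 5 detected ligands and 2 of 3 detected receptors higher in fibroblasts and medians of 3.45 and 3.89. Hbegf, Ereg and Nrg1 stood at 65.2, 15.5 and 11.4 TPM against 0.674, 0.0472 and 0.132, and Egfr and Erbb2 at 22.2 and 19.5 against 0.197 and 0.377. Of 6 detected neurotrophin and GDNF ligands, 3 were higher in fibroblasts, with a median of 2.5, and Bdnf and Ntf3 stood at 29.6 and 7.78 TPM there and were listed at 0 in macrophages. Of the 3 detected receptors of that family only Gfra1 differed by the rule, at 10.5 TPM against 0.105, and the receptor median of 1.19 lay at percentile 66.05 of matched random lists. Among the angiopoietin, GAS6 and pleiotrophin ligands, Ptn, Pros1, Mdk and Angpt4 were higher in fibroblasts, at 310.1, 77.0, 30.7 and 9.69 TPM against 0.0638, 9.52, 6.32 and 0.0429, with a family median of 2.41. Their receptors included Axl, Ptprz1 and Tyro3, higher in fibroblasts at 294, 18.6 and 14.7 TPM against 64.6, 0 and 0.362. Axl, with a log2 ratio of 2.17, and Mdk lay close to the 4-fold limit and fall below it under median-of-ratios scaling. Mertk, which macrophages use to take up dying cells, was higher in macrophages at 22.1 against 4.59, also close to the 4-fold limit. The median of the 5 detected receptors was 2.17.

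The second question the series allows is which ligand genes of 1 cell type meet an expressed receptor gene of the other, where expressed means 5 TPM or more. Of 92 fixed ligand and receptor pairs, 17 ran from fibroblast ligand to macrophage receptor and 18 from macrophage ligand to fibroblast receptor. Within fibroblasts 32 pairs were expressed, within macrophages 19, and 39 in no combination. Genes of these pairs that earlier paragraphs do not name were named after their values were seen. Csf1 with Csf1r was a fibroblast to macrophage pair, at 395 and 640.0 TPM, and it was also complete within macrophages through the 30.5 TPM of Csf1 there. Cxcl12 with Cxcr4, at 533 and 71.2 TPM, and Cx3cl1 with Cx3cr1, at 23.5 and 35.0 TPM, were the 2 pairs that ran from fibroblast to macrophage and in no other combination. In the opposite direction the 4 such pairs were Pdgfb with Pdgfra and with Pdgfrb, and Osm, encoding the cytokine oncostatin M, with Osmr and with Lifr. Osm stood at 14.2 TPM in macrophages, and Osmr and Lifr at 57.2 and 9.42 in fibroblasts. Pdgfa with Pdgfra was expressed both within fibroblasts and from macrophage to fibroblast. Igf1 with Igf1r did the same, since fibroblast Igf1, at 6.57 TPM, also passed the minimum. Igf2 with Igf2r, at 901 and 45.9 TPM, was complete within fibroblasts and from fibroblast to macrophage. The 4 pairs expressed in both directions were complete in all 4 combinations: Gas6 with Axl, Tgfb1 with Tgfbr2, Tnfsf12 with Tnfrsf12a, and Vegfa with Nrp1. With the minimum lowered to 1 TPM, 31 pairs ran from fibroblast to macrophage and 29 in the opposite direction. These are transcript pairs, and neither protein nor signalling was measured.

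**Figure D2:**
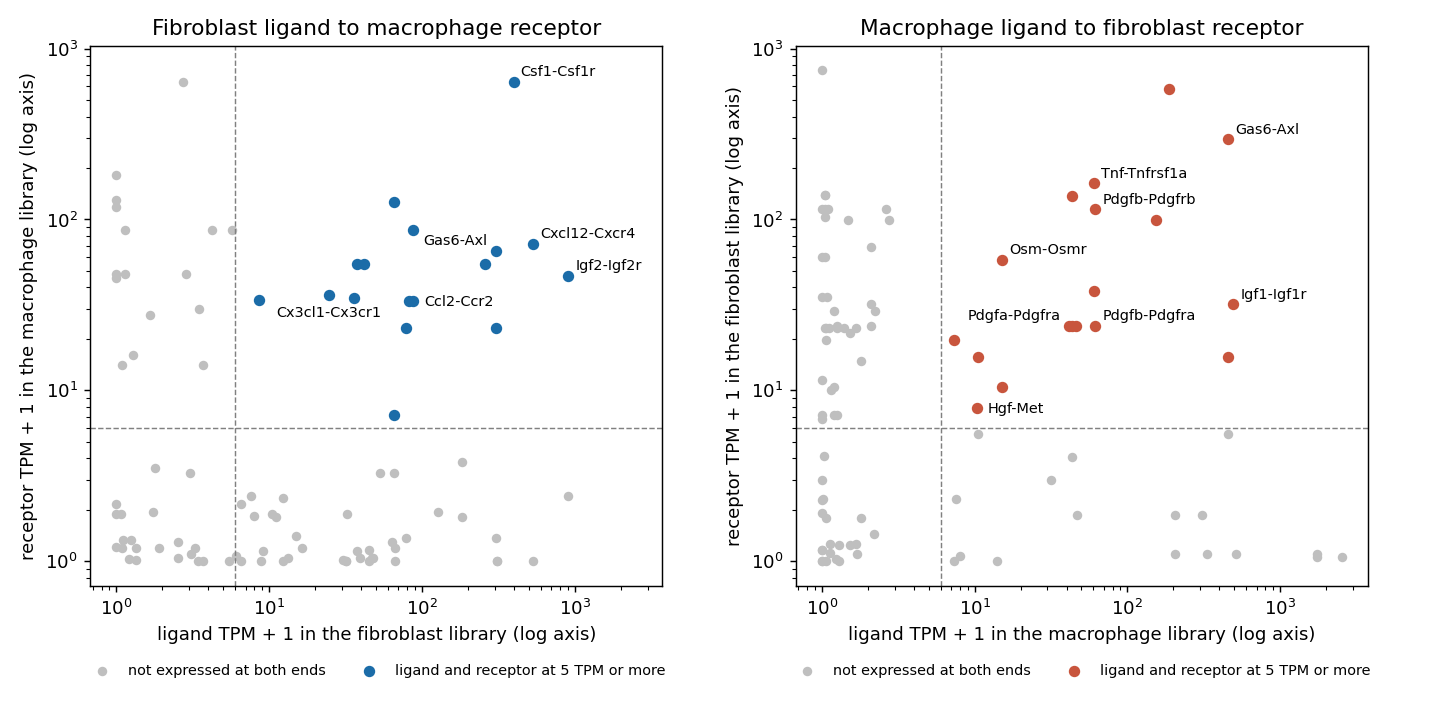
Each point is 1 of 92 ligand and receptor pairs, with ligand TPM plus 1 in the sending library on the horizontal log axis and receptor TPM plus 1 in the receiving library on the vertical log axis; dashed lines mark 5 TPM. Coloured points passed 5 TPM at both ends, 17 from fibroblast to macrophage (left) and 18 from macrophage to fibroblast (right), and Csf1 with Csf1r stood highest among the coloured points on the left.

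Chemokine genes past the size rule lay more often on the macrophage side, and cytokine genes were divided. Of 21 detected chemokine genes, 11 were higher in macrophages and 4 in fibroblasts, with a median log2 ratio of -2.81. The monocyte attractant genes Ccl2 and Ccl7 reached 2517 and 1731 TPM in macrophages and were also expressed in fibroblasts, at 81.6 and 86.0. Ccl9 stood at 512 TPM against 3.19. The 4 fibroblast chemokines were Cxcl12, Cxcl5, Cx3cl1 and Cxcl1, at 533, 81.9, 23.5 and 7.95 TPM against 0.529, 0, 0.712 and 0.578. Of 19 detected cytokine genes, 8 were higher in macrophages and 6 in fibroblasts, with a median of -1.55. Macrophages held Tnfsf12 at 187 TPM against 35.1, Tnf at 59.1 against 0, Tnfsf9 at 30.3 against 5.59 and Il18 at 22.0 against 1.35. Fibroblasts held the interleukin 6 family members Clcf1, Ctf1 and Cntf at 41.3, 8.96 and 8.58 TPM against 0.110, 0 and 1.01, and Tnfsf11, encoding the osteoclast factor RANKL, at 7.55 against 0. Clcf1 was listed on 2 identical rows, which were added, so its value may be doubled, and a single row of 20.7 TPM gave a log2 ratio of 4.36 in place of 5.25. Of 32 detected cytokine and chemokine receptor genes, 10 were higher in fibroblasts, 11 in macrophages and 11 in neither, with a median of -0.74. The interleukin 33 receptor gene Il1rl1, Tnfrsf12a, the shared interleukin 6 family subunit Il6st and Osmr were higher in fibroblasts, at 743, 576, 247.0 and 57.2 TPM against 2.53, 33.6, 23.6 and 0.215. Il10rb, Il2rg, Ccr1 and Cxcr4 were higher in macrophages, at 272, 145, 85.9 and 71.2 TPM against 34.2, 1.10, 0.101 and 0.239.

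The gene groups around these factors separated the libraries by function. Some of these lists share members with the marker lists and are not independent of them. The matrix list, for example, holds the fibroblast markers Col1a1, Col1a2, Col3a1, Sparc and Lox. Of 35 extracellular matrix genes, 33 were higher in fibroblasts, with a median of 7.45 and Thbs1 highest of them at 4977 TPM against 39.2. Of 14 genes listed as contractile and cytoskeletal, 12 were higher in fibroblasts, with a median of 7.75. Among them were Tagln at 3219 TPM against 10.6 and Tpm1 at 2918 against 81.0. The list also holds Ctgf, at 1407 against 3.88, and Cyr61, whose products are not contractile. Without Ctgf and Cyr61 its median was 6.70. Of 18 genes listed as proteases and their inhibitors, 11 were higher in fibroblasts and 3 in macrophages, with a median of 5.83. The list members Timp2, Timp1 and Serpinf1 stood at 1907, 1565 and 994 TPM in fibroblasts, against 269.8, 7.57 and 5.56. The proteases Plau, Mmp12 and Mmp8 stood at 739, 182 and 7.83 in macrophages, against 119.8, 2.82 and 0.279, and Mmp8, a neutrophil collagenase, was higher in the library where 5 of 11 neutrophil genes were higher. Of 36 detected Wnt, Hedgehog and Notch genes, 18 were higher in fibroblasts, with a median of 2.26, including Dkk3, Rspo2, Smo and Fzd2 at 122, 81.3, 63.1 and 54.4 TPM against 0.0585, 0, 1.09 and 0.0267. The Notch ligand gene Jag2 was the 1 member higher in macrophages, at 6.87 against 0.0732.

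In the lists of lysosomal, pattern receptor, complement, MHC class II, interferon-stimulated and lipid handling genes, most members past the size rule were higher in macrophages. Of 26 lysosomal genes, 13 were higher there and 1 in fibroblasts, with a median of -2.00. Ctsd reached 13893 TPM against 2115, Ctsb 6133 against 417, Psap 5756 against 1123 and Gpnmb 3696 against 184, whereas Ctsk, a collagen-degrading protease, was higher in fibroblasts at 153 against 2.26. Of 22 Toll-like and pattern receptor genes, 16 were higher in macrophages and 0 in fibroblasts, with a median of -3.57, and Msr1, Clec4d, Cd36 and Cd14 stood at 591, 573, 486 and 404 TPM against 0.568, 0.237, 2.27 and 1.78. Of 21 complement and Fc receptor genes, 15 were higher in macrophages and 2 in fibroblasts, with a median of -6.81. The 2 were the initiating protease genes C1s1 and C1ra, at 39.0 and 38.1 TPM against 0.0340 and 5.07, while the C1q subunits they act with were macrophage genes. This list shares members with the macrophage markers, among them C1qa, C1qb, C1qc, Fcer1g and Itgam. All 6 detected MHC class II genes were higher in macrophages, with a median of -3.40, at modest levels led by H2-DMb1 at 65.0 TPM against 4.79 and Cd74 at 49.1 against 2.76, with H2-DMa at 30.6 against 2.06 and H2-Aa at 21.3 against 1.06. Of 20 interferon-stimulated genes, 17 were higher in macrophages, with a median of -3.88, including Bst2, Irf7, Rtp4 and Oas1a at 1841, 327, 214 and 199 TPM against 97.9, 1.63, 7.83 and 0.302. Of 16 genes of cholesterol efflux and lipid handling, 9 were higher in macrophages, with a median of -3.07. Among them were Apoe at 3368 TPM against 43.1, Fabp5 at 1489 against 157, Trem2 at 1452 against 1.41 and Plin2 at 893 against 91.9.

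**Figure D3:**
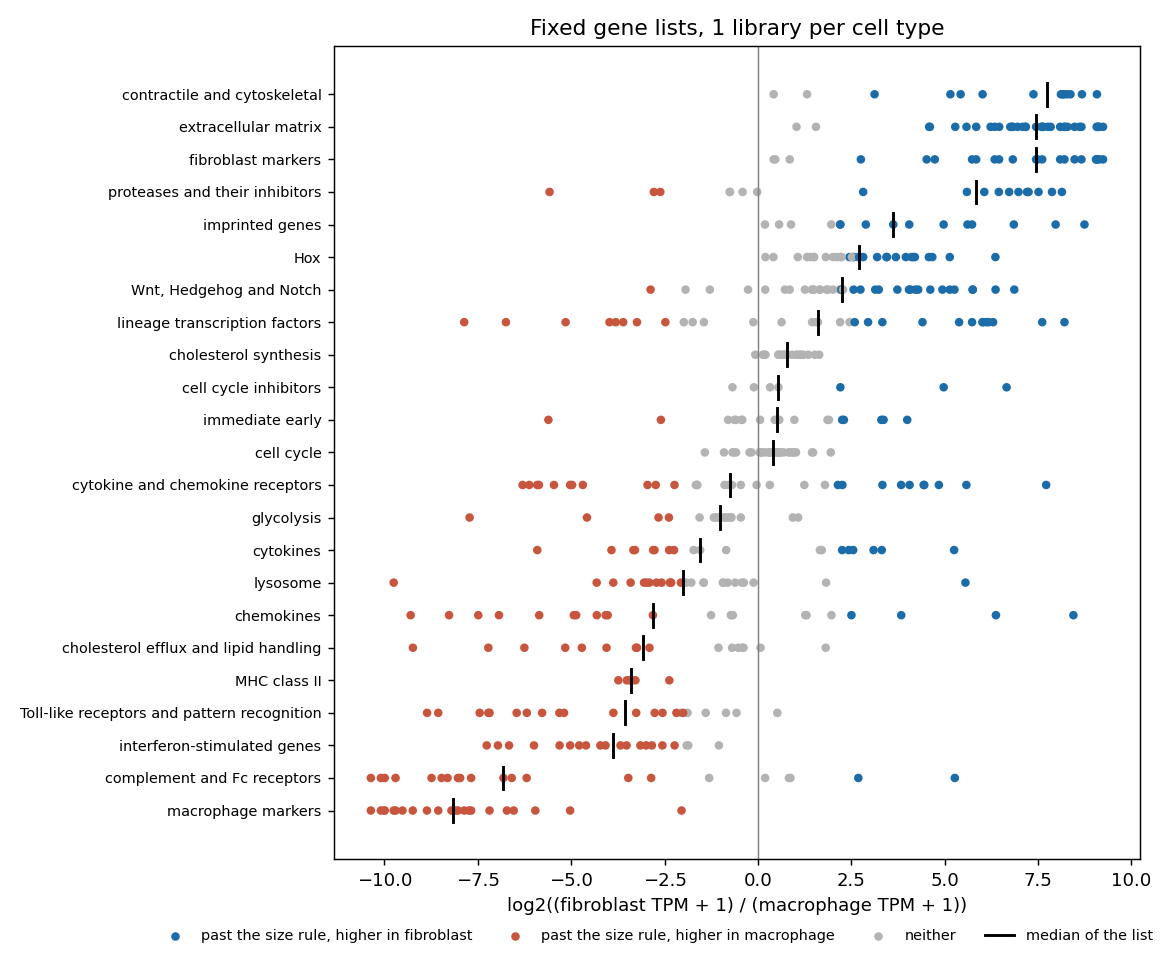
Each row is a fixed gene list and each point a member at 1 TPM or more in at least 1 library, placed by the log2 ratio of fibroblast over macrophage TPM with 1 added to each value; black bars are list medians and colours mark genes past the size rule. The contractile and cytoskeletal list, with a median of 7.75, lies farthest to the fibroblast side. Without its members Ctgf and Cyr61 its median was 6.70, below the 7.45 of the matrix list and of fibroblast markers. Macrophage markers, with a median of -8.15, lie farthest to the macrophage side.

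Transcription factor genes differed by lineage. Of 31 detected lineage factors, 13 were higher in fibroblasts and 8 in macrophages, with a median of 1.61. Prrx2, Prrx1, Tead1 and Snai1 stood at 384, 227, 89.8 and 75.7 TPM in fibroblasts, against 0.303, 0.168, 0.156 and 0.191. Spi1, which encodes the myeloid factor PU.1, stood at 355 TPM in macrophages against 0.529, with Irf5 and Irf8 at 168 and 141 against 3.75 and 0.319. Of 31 detected Hox genes, which record position along the body and limb, 18 were higher in fibroblasts and 0 in macrophages, with a median of 2.69. The distal limb and genital gene Hoxd13 was the highest at 84.4 TPM, followed by Hoxa10, Hoxc6 and Hoxc8 at 36.3, 27.6 and 22.9. Of 15 detected imprinted genes, 11 were higher in fibroblasts and 0 in macrophages, with a median of 3.62. Beside Igf2 they included Grb10, Mest and Impact at 316, 148 and 75.2 TPM against 0.265, 0.287 and 15.6. Of 21 listed imprinted genes, 17 had a row under their symbol, and H19, Meg3, Rian and Mirg had none.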

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

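The subtraction of marker shares was the 1 alternative chosen after the data were seen. The pseudocounts, which by construction set the size of ratios against low values, mattered most. Of the ratios of 199 named genes, 0.1 moved 108 and 5 moved 144 by over 1.5-fold, and of 55 list medians 36 and 37. This 1.5-fold is a change of the ratio itself and not of its log2 value. Protein-coding genes alone moved 1, that of the contractile list, from 7.75 to 6.70, since the symbols Ctgf and Cyr61 had no match in the annotation and dropped out. Subtraction of marker shares moved 25 named ratios, and the highest single row of a gene moved 2, Clcf1 to 4.36 and Lilrb4a to -9.19. No named ratio reversed under these settings or the scalings, but this was largely fixed in advance. A pseudocount added to both values cannot reverse a ratio. Median-of-ratios scaling took the median log2 ratio of genes expressed in both libraries only from 0.18 to 0.013. The threshold and the minimum do not enter ratios or medians. The list median of genes used in every cell reversed, from 0.08 to -0.0995, under median-of-ratios scaling. Of the list percentiles 43 stayed and 9 moved without matching.

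A 2-fold threshold called 2637 genes higher in fibroblasts and 1698 in macrophages, and a pseudocount of 5 called 896 and 652 and left 3 growth factor ligands higher in macrophages; both follow from how strict the rule is. The pair counts depended on the minimum. At 1 TPM 31 pairs ran from fibroblast to macrophage and 29 in the opposite direction. With no minimum the counts were 72 and 74, with 79 within fibroblasts and 68 within macrophages, because any value above 0 then counts as expressed. Rescaling without mitochondrial and the 50 highest genes gave 1676 and 1073 genes, and subtraction of marker shares 1604 and 982. Protein-coding genes alone and rescaling gave no value for named genes and lists that they leave out. No replicate could be left out and no paired analysis was possible because each group had 1 library. Depth is unknown, so the precision of values near 0 cannot be stated.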

Other observations

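All tests of explanations given here, and the subtraction of marker shares, were chosen after the values were seen. None of 30 cell cycle genes differed by the rule, with a median log2 ratio of 0.40 toward fibroblasts, at percentile 91.86 of matched random lists. The members with the highest values ran against this median, Pcna at 201 TPM in fibroblasts against 539.9 in macrophages and Ccnd1 at 245 against 383. The cyclin-dependent kinase inhibitor genes Cdkn2a, Cdkn2b and Cdkn1c, 3 of 7, were higher in fibroblasts at 305, 106 and 18.4 TPM against 2.03, 2.40 and 3.19, with a list median of 0.55. Of 18 immediate early genes, 5 were higher in fibroblasts and 2 in macrophages, with a median of 0.51. The inhibitor and immediate early medians lay at percentiles 85.99 and 89.12 of matched random lists. Fosl2, Klf4, Egr1 and Fosl1 stood at 68.6, 56.0, 40.4 and 37.0 TPM in fibroblasts against 13.6, 10.6, 3.02 and 1.38. Atf3 and Fos stood at 168 and 40.0 in macrophages against 2.47 and 5.78. None of 20 cholesterol synthesis genes differed by the rule, with Fdps at 292 TPM against 154 and Msmo1 at 179 against 116. Their median of 0.77 lay at percentile 99.92 of matched and 96.54 of unmatched random lists. Random genes were drawn independently, so a list whose genes vary together can reach an extreme percentile from 1 library each. Of 18 glycolysis genes, 4 were higher in macrophages and 0 in fibroblasts, with a median of -1.01. These were the hexokinase gene Hk3 at 258 TPM against 0.227, the lactate exporter gene Slc16a3 at 238 against 9.01, Pfkp at 132 against 24.5 and Pdk1 at 56.8 against 8.12.

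Markers of other cell types were mostly low. In the fibroblast library, 3 of 5 detected muscle genes were higher (Acta1, Tnnt2 and Des at 70.8, 6.98 and 6.11 TPM against 0.721, 0.881 and 0), although Acta1 shares long coding stretches with the abundant Acta2 and is uncertain. Of 4 detected neural genes, 3 were higher there (Stmn2, Map2 and Tubb3 at 39.7, 35.1 and 20.8 against 0, 0.169 and 0.163), as were 2 of 3 cartilage and bone genes (Col2a1 and Sox9 at 6.11 and 5.03 against 0 and 0) and the epithelial keratin gene Krt19 (23.2 against 0), 1 of 2 detected. Of 8 mast cell and basophil genes, 2 were detected, both higher in fibroblasts: Mcpt8 at 30.8 TPM against 0 and Gata2 at 14.5 against 0.0629. None of 3 detected endothelial genes differed by the rule, with Kdr at 3.10 against 6.14 and Pecam1 at 1.97 against 1.33, and none of 8 erythroid genes was detected. The dendritic cell list had 1 detected gene, Itgax, at 6.96 in macrophages against 0.0971, and the lymphocyte list had 1 of 4 detected genes higher in macrophages, Ighm at 10.98 against 0.117. In the osteoclast list, 1 of 6 detected genes differed, Ctsk on the fibroblast side. The 13 mitochondrial genes had a median of 0.84 with none past the rule, and mt-Co3 and mt-Atp8 stood at 7904 and 7827 TPM against 4407 and 4993. Of 16 genes used in every cell, B2m alone differed, at 7126 TPM in macrophages against 1333, and the median of 0.08 turned to -0.0995 under median-of-ratios scaling. The 4 Y-linked genes were present in both libraries with none past the rule, Eif2s3y at 27.5 and 50.9 TPM and Ddx3y at 21.5 and 27.0. The mitochondrial leucyl-tRNA synthetase gene Lars2 stood at 2568 TPM in fibroblasts and 6453 in macrophages, while 16 other genes of mitochondrial aminoacyl-tRNA synthetases, matched by name, had medians of 12.1 and 10.5 and a highest value of 41.1 and 30.9. Whether the Lars2 values are its own transcript or other RNA assigned to it could not be tested here, so they are uncertain.

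Markers of each cell type were present at a low level in the other library: the 10 macrophage markers at 1000 TPM or more stood in the fibroblast library at 0.0459% to 0.306% of their macrophage value (median 0.0780%), a span of 6.67-fold. The 7 fibroblast markers past the rule at 1000 TPM or more stood in the macrophage library at 0.0896% to 0.523% (median 0.139%), a span of 5.84-fold, which leaves out Vim and S100a4, at 74.7% and 72.5%. Over all 42 genes past the rule at 1000 TPM or more in macrophages the shares ran to 24.4% (median 4.67%, a 530.4-fold span), and over the 25 such fibroblast genes to 24.5% (median 0.263%, 274-fold), while 2 of 80 genes past the rule at 500 TPM or more in macrophages, Ccl12 and Wfdc17 at 629 and 535 TPM, were listed at 0 in fibroblasts. Reads or RNA carried between the libraries, a few cells of the other type and low expression in the cells themselves cannot be told apart, since the spans were looked at before a limit was set for them and depth is unknown. Macrophages that passed the sort through low sort genes would give these genes lower shares than other markers. The 3 sort genes had instead a median share of 0.159%, 1.66 times the 0.0961% of the other macrophage markers. Such macrophages still stay open, since the sort genes stood at only 0.352 to 0.483 TPM in 1 fibroblast library, without an unsorted library to compare.

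Granulocyte genes were seen in the macrophage library, for which the labels name no sort. Of 11 neutrophil genes, none of them in another list, 9 reached 1 TPM there and were higher than in fibroblasts, and 5 passed the size rule, with a list median of -2.63. The highest were S100a9 and S100a8, which encode calprotectin, at 268 and 157 TPM against 0 and 1.85, followed by the granule protein genes Ngp and Ltf at 48.3 and 12.0 against 0. The members below 1 TPM, named after their values were seen, were Ly6g, listed at 0, and Cxcr2 at 0.563. Granulocytes or their precursors among the macrophages and expression by the macrophages themselves cannot be told apart, since the count of 9 is the pattern itself and no sorted macrophage library was analysed here.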
